A study of Homo sapiens with 12 samples.

How the data were processed

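The samples were THP1 cells, a human monocytic leukaemia line, transduced with an inducible vector for an shRNA against RUVBL2. There were 3 samples with doxycycline (1 µg/ml) and 3 in medium alone at each of day 2 and day 4, 12 in all. Total RNA was extracted with a column kit and libraries were made with the TruSeq RNA v2 kit, per the labels' protocols; that kit does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart. The day of each sample was taken from its title and time point label, since the treatment text states 4 days for every sample.

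The reads were processed by the authors, and the deposited tables are the start of everything reported. Per the submitters' processing notes the tools were bcl2fastq 2.19, Trimmomatic, Bowtie2, Picard, featureCounts and DESeq2, with genome build hg38; their order, settings and gene annotation are not given in the sources used here. Each deposited table holds for 26485 gene symbols the authors' mean normalised count over the 6 samples of that day, a signal on the scale of counts with 2 decimals. The log2 fold change in the authors' deposited tables has 3 decimals. The p-value and adjusted p-value in the authors' deposited tables are those of the authors' test. At day 2 a mean of 0 was listed for 8708 genes, 17775 had a p-value and 13074 an adjusted p; at day 4 these numbers were 7471, 19011 and 12513. The genes with a p but no adjusted p had a mean of at most 5.27 at day 2 and 11.99 at day 4. Benjamini-Hochberg adjustment of the deposited p-values over the genes with an adjusted p gave back the deposited values to within 6.8e-06. A fold change without a p was listed for CLEC5A and SPP1 at day 2 and for RMRP, RN7SK and RPPH1 at day 4.

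The tables hold no column per library. The count-based tests written down before the data were examined could therefore not be run, and the fallback written with them was used: the authors' adjusted p at 0.05 is the call for each gene and day. The column headers give no direction. The comparisons are titled no doxycycline versus doxycycline, an order that read literally is the reverse of the one adopted here. RUVBL2 was negative and MIR30A positive on both days, and positive values were read as higher with doxycycline on that ground.

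The standard error of each fold change was recovered by dividing its size by the normal quantile of its two-sided p-value. This was direct for 95.9% of genes with an adjusted p at day 2 and 97.4% at day 4; for fold changes under 0.01 the running median over 201 genes of like mean count was used. The median recovered standard error was 0.163 at day 2 and 0.142 at day 4. For genes with a mean from 100 to 300 the medians were 0.177 and 0.156, which is the precision the authors' tables carry at that level. Intervals for folds are normal 95% intervals. Depth per sample is unknown.

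The difference between days was tested per gene as the difference of the log2 fold changes over the root of their summed squared standard errors, with two-sided normal p-values and Benjamini-Hochberg adjustment over 12088 genes. Overlaps of calls were tested with Fisher's exact test. For gene lists, cameraPR of limma 3.58.1 (R 4.3.3) was run on the signed normal quantiles of the deposited p-values of all genes with an adjusted p, with a preset correlation of 0.01 between genes, two-sided, and Benjamini-Hochberg adjustment over the lists. The 26 lists, the named gene rule, the tests and most alternatives were fixed before the data were examined. Of the 26 lists 25 had at least 5 members with an adjusted p on each day; the 13 symbols of the mitochondrial genome list matched no row and that list was not tested. The lists cover RUVBL2 partner complexes (R2TP and TTT, INO80, SRCAP and TIP60, PIKK kinases, snoRNPs), ribosomes and their assembly, leukaemia and HOXA genes, monocyte, granulocyte and other blood lineages, the cell cycle, p53, apoptosis, stress responses, metabolism, interferon, NF-kB, histones and lysosomes. The list of other blood lineages was meant to mark cells that a THP1 culture should lack. Some of its members were nonetheless counted, such as NKG7 (mean normalised count 435.86 at day 2 and 121.58 at day 4 in the authors' deposited tables). The list therefore does not serve as a control for absent cells.

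Named genes were chosen by rule: RUVBL2; for each day the 6 steepest rises and 6 steepest falls past the threshold with a mean of at least 100; RUVBL1, MYB, MYC, BCL2, HOXA9, MEIS1, CD14, ITGAM, CSF1R and CDKN1A; from each list up to 4 members past the threshold with the largest change, or up to 2 with the highest mean; and, among genes past the threshold of that test with a mean of at least 100 on both days, the 5 largest and 5 smallest differences between days. Genes named outside the rule were chosen after their values were seen: LHB and SRFBP1 as overlapping genes, and those that the closing section names as such. The 31 gene families of the closing section were picked after the fold changes were seen. Coordinates are 1-based on hg38 from GENCODE 29, matched by symbol; 24526 of 26485 symbols matched, 701 of them through older symbols in RefSeq.

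The scripts used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated data. For the difference between days, 12088 simulated genes with 200 true differences gave 93 calls, 3 of them false and 0 with the wrong sign; 19% of the differences of 0.5 and 71% of those of 1 were called. Recovered standard errors were off by a median of 0.141%. The simulated fold changes were drawn gene by gene from normal distributions with the recovered standard errors. These results therefore check the calculation. They cannot show whether those errors are right for 3 samples per group, or how the test behaves with correlated genes. In the list test 1 shifted list had adjusted p = 6.91e-06 and 0 of the others passed, 24 lists being tested. The simulated genes of that list test were independent. It therefore does not show how often lists of correlated genes pass without a shift.

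The alternatives were other thresholds, a size threshold, adjustment over other sets of genes, a mean of at least 100, recentring on the median, correlations of 0.05 and 0.3, ranks or fold changes as the list statistic, Fisher's exact test of list members, and removal of trends on length and GC content by lowess (span 0.3). Length was that of all exons of a gene merged, and GC content that of its longest transcript. Alternatives that need library columns were left out.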

Results

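THP1 is a human cell line from an acute monocytic leukaemia. The cells carried TRIPZ, a lentiviral vector from which doxycycline switches on a short hairpin RNA (shRNA) set in a microRNA backbone, here directed against RUVBL2. RUVBL2 is an ATPase that works with RUVBL1 in the R2TP chaperone complex and in the INO80, SRCAP and TIP60 chromatin remodelling complexes. RNA was sequenced from 12 samples: 3 with doxycycline at 1 µg/ml and 3 in medium alone at day 2, and as many of each at day 4. The question was which transcripts change once the hairpin against RUVBL2 is switched on, early and later. Each day is described by 1 deposited table, which gives the authors' mean normalised count, log2 fold change, p and adjusted p for each of 26485 genes. Values per library were not analysed here, so the depth of each sample is unknown. The authors' mean normalised counts summed to 1.48 times as much at day 2 as at day 4. All 12 samples carried the RUVBL2 vector, so any effect of doxycycline itself or of hairpin expression is part of every comparison. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

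RUVBL2 itself fell on both days. In the authors' deposited table its log2 fold change was -2.81 at day 2 (adjusted p = 1.89e-65), which is 14.3% of the level without doxycycline (95% interval of the fold 0.115 to 0.177). At day 4 the authors' deposited table gave -1.85 (adjusted p = 3.76e-59), or 27.7% of the level without doxycycline (interval of the fold 0.238 to 0.322). The gene spans chromosome 19, positions 48993448 to 49015995 on the plus strand of hg38, and its 3' end overlaps LHB on the other strand, whose mean normalised count was 0.15 and 0.48 in the authors' deposited tables. MIR30A, whose hairpin is the backbone used in TRIPZ, had the lowest p-value of either day in the authors' deposited tables, with log2 fold changes of 6.03 at day 2 and 5.22 at day 4. The sign of these genes sets the reading of every fold change here as doxycycline over medium alone, since the column headers do not state it. RUVBL1, the partner ATPase, stood at -0.19 in the authors' deposited table at day 2 (adjusted p = 0.567) and fell at day 4, to -0.51 (adjusted p = 3.59e-07).

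At day 2, with RUVBL2 at its lowest, genes of the type I interferon response and of the integrated stress response and amino acid synthesis stood higher as lists, and genes of DNA replication, mitosis, cholesterol synthesis and the ribosome stood lower as lists. Of 13074 genes with an adjusted p in the authors' deposited table, 194 (1.5%) passed 0.05, of which 142 were higher and 52 lower with doxycycline. Their median log2 fold changes were 0.70 and -0.50. A change of at least 1 on the log2 scale was reached by 52 of them, 46 higher and 6 lower.

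Among genes with a mean normalised count of at least 100, the steepest rises at day 2 in the authors' deposited table were those of LOX (6.04) and MIR30A (6.03). CHAC1 (2.14), ANTXR1 (2.07), RDH10 (1.93) and IER5L (1.88) came next in the authors' deposited table, with recovered standard errors of 0.31, 0.16, 0.26 and 0.16. LOX encodes lysyl oxidase, which crosslinks collagen and elastin, CHAC1 degrades glutathione, ANTXR1 is an anthrax toxin receptor and RDH10 oxidises retinol. LOX lies on chromosome 5 at 122063195 to 122078360, minus strand, and overlaps SRFBP1 on the other strand, which stood at 0.40 in the authors' deposited table (adjusted p = 0.341). After RUVBL2, the steepest falls in the authors' deposited table were those of NAV3 (-1.21), LINC00925 (-1.01), VIT (-0.98), MS4A3 (-0.84) and MARC1 (-0.81). MS4A3 is a membrane protein of granulocyte and monocyte progenitors.

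Of 32 measured type I interferon response genes, 12 rose and none fell at day 2, and 20 did not pass. Adjusted over the list alone, 19 rose. Examples in the authors' deposited table were IFI44L (2.05, adjusted p = 0.00346), MX1, which blocks viral replication (1.52, 4.91e-08), IFI6 (1.35, 3.43e-16) and OAS3, a sensor of double-stranded RNA (1.22, 4.98e-10). The list median was 0.70 and the list test (cameraPR) gave adjusted p = 4.7e-32. Of 42 genes of the integrated stress response and amino acid synthesis, 6 rose and none fell, 15 rose adjusted over the list alone, and 41 had a positive fold change. The median was 0.52 (cameraPR adjusted p = 4.65e-20). Beside CHAC1, STC2 (1.91, adjusted p = 0.00502), NUPR1 (1.17, 0.0214) and SESN2 (0.99, 0.00506) were, with it, the largest of those that rose in the authors' deposited table, and ATF4, the transcription factor that drives this response, rose by 0.59 (adjusted p = 0.0171). The standard errors of this list had a median 1.55 times that of genes of like mean count, above all 10000 random lists of its size. A far smaller ratio, 1.05 for the cytosolic ribosomal proteins at day 2, was also above all 10000. The lysosome and autophagy list also stood higher (median 0.14, cameraPR adjusted p = 1.98e-04), with 1 member of 38 past the threshold, CTSL, a lysosomal protease, at 0.44 in the authors' deposited table, and 2 adjusted over the list alone. That call was lost with the fold change as the statistic (adjusted p = 0.0907) and with Fisher's exact test of called members (adjusted p = 1.00).

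The cell cycle lists stood lower at day 2, with few members past the threshold. Of 53 genes of G1/S and DNA replication, 3 fell and 50 did not pass, while all 53 had a negative fold change and 15 fell adjusted over the list alone (median -0.26, cameraPR adjusted p = 1.45e-22). In the authors' deposited table RRM2 and RRM1, the subunits of ribonucleotide reductase, stood at -0.38 (adjusted p = 0.0183) and -0.34 (0.0229), and MCM4, part of the replicative helicase, at -0.29 (0.0395). Of 60 G2/M and mitosis genes, 7 fell, 14 adjusted over the list alone, and 59 were negative (median -0.23, adjusted p = 2.91e-24). KIF15, a mitotic kinesin, was at -0.60 in the authors' deposited table (adjusted p = 5.66e-04) and AURKB, a mitotic kinase, at -0.54 (0.0347). Of 76 cytosolic ribosomal protein genes, 2 fell, RPS12 (-0.43, adjusted p = 0.0151) and RPS20 (-0.33, 0.0251) in the authors' deposited table, 4 fell adjusted over the list alone, and 74 were negative (median -0.17, cameraPR adjusted p = 7.64e-18). Fisher's exact test of called members did not pass for this list (adjusted p = 0.229). Of 24 genes of cholesterol synthesis and uptake, 2 fell, ACAT2 (-0.60, adjusted p = 2.4e-04) and FDPS (-0.42, 0.0493) in the authors' deposited table, 5 fell adjusted over the list alone, and the median was -0.26 (cameraPR adjusted p = 7.35e-09). Their standard errors had a median 1.28 times that of genes of like mean count. With a correlation of 0.3 between genes, 4 of the 10 list calls of day 2 held, those of the interferon, integrated stress response, G1/S and G2/M lists, while the ribosomal protein and cholesterol lists each had adjusted p = 0.0726 and the lysosome list 0.623.

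For 3 other lists with negative medians the call at day 2 was lost when the preset correlation between genes was raised from 0.01 to 0.05, and the correlation itself could not be estimated without values per library. These were the heat shock proteins and chaperonin (median -0.08, 0 of 28 passed; adjusted p = 0.00403, then 0.06), the nuclear encoded oxidative phosphorylation subunits (-0.06, 1 of 61 fell, UQCRH; 9.36e-04, then 0.0613) and the INO80, SRCAP and TIP60 subunits (-0.06, 0 of 35 passed; 0.0391, then 0.201). The monocyte and macrophage differentiation list missed the threshold (median 0.16, cameraPR adjusted p = 0.0885) and passed it among genes with a mean of at least 100 (adjusted p = 0.0258). Of its 42 members 3 rose, ITGAX (0.49, adjusted p = 0.0461), CSF1R (0.47, 0.0293) and CTSL in the authors' deposited table, and none fell. Its standard errors had a median 1.47 times that of genes of like mean count, above all 10000 random lists, and ITGAM, the CD11b integrin, stood at 1.09 with an adjusted p of 0.54 in the authors' deposited table. At day 4 the ratio of this list, 1.03, was also above all 10000 random lists. The rank alone therefore does not set day 2 apart. CD14, a monocyte surface marker, stood at 0.24 (adjusted p = 0.997, recovered standard error 1.17) in the authors' deposited table. Of the 42 members, 28 had a positive and 14 a negative fold change at day 2. S100A8 (-0.88), LYZ (-0.75) and S100A9 (-0.74) were among the negative ones, with recovered standard errors of 1.23, 0.64 and 1.16.

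The remaining lists did not pass at day 2. R2TP and TTT chaperone genes (0 of 17 passed, adjusted p = 0.756), PIKK kinases (0 of 6, 0.108), snoRNP proteins (0 of 12, 0.285) and ribosome biogenesis factors (0 of 37, 0.365) are groups whose protein products RUVBL2 is known to help assemble or that work downstream of these complexes. The leukaemia gene list around MYB and MYC (adjusted p = 0.122) had 1 of 32 members past the threshold, FLT3, a growth factor receptor, at -0.63 in the authors' deposited table. In the HOXA and MEIS1 programme (0.931) MBNL1 rose and FLT3 fell, and 25 of 27 did not pass. MYB (-0.03), MYC (0.08), BCL2 (0.00) and HOXA9 (0.30) did not pass in the authors' deposited table, the lowest adjusted p being 0.863 (HOXA9), and MEIS1 had a mean normalised count of 0.31 and no adjusted p. Of 29 p53 target genes (0.122, and 0.0337 by Fisher's exact test of called members), SESN2, CCNG1 (0.73) and CD82 (0.65) rose in the authors' deposited table, while CDKN1A, the p21 cell cycle inhibitor, stood at 0.51 (adjusted p = 0.145). None of the members tested passed in the granulocyte (13, list adjusted p = 0.365), other blood lineage (10, 0.849), apoptosis (35, 0.756), NF-kB (21, 0.849), glycolysis and hypoxia (31, 0.905) and histone (7, 0.849) lists. In the endoplasmic reticulum chaperone list (0.518) CALR alone of 25 passed, at -0.43 in the authors' deposited table. Adjusted over the list alone, the counts differed for p53 targets (5 rose, 1 fell), oxidative phosphorylation (2 fell), and the remodelling, PIKK and NF-kB lists (1 fell in each). In the HOXA, endoplasmic reticulum and NF-kB lists the median was above 0 (0.07, 0.02 and 0.06) while the mean (-0.02, -0.02 and -0.03) and the test pointed down.

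**Figure D1:**
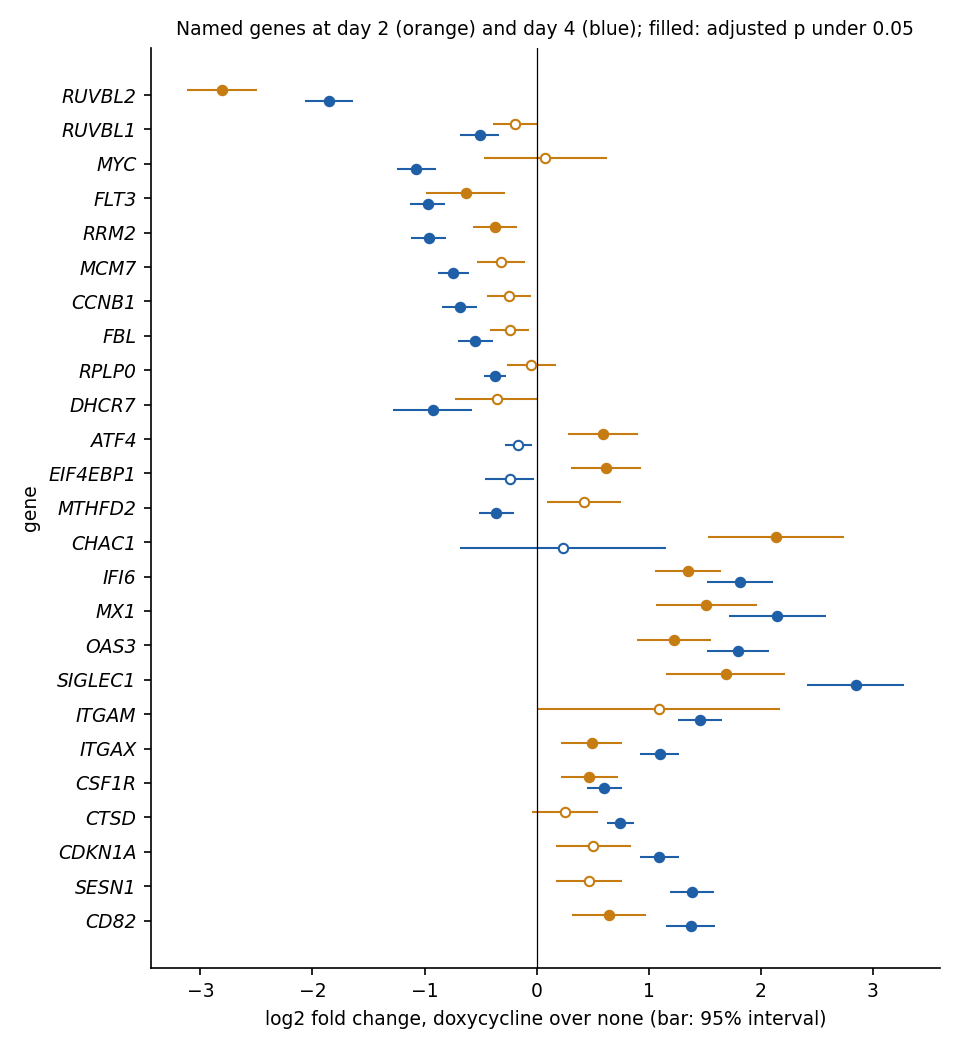
Log2 fold change (doxycycline over medium alone) of 25 named genes in the authors' deposited tables at day 2 (orange) and day 4 (blue), with 95% intervals from the recovered standard errors and filled points where the authors' adjusted p was under 0.05. RUVBL2 is lowest on both days, ATF4 and EIF4EBP1 are filled at day 2 only, and ITGAM has a wide interval at day 2.

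At day 4 the response covered 2878 of 12513 genes in the authors' deposited table (23.0%), 1469 higher and 1409 lower. As lists, interferon, lysosome, macrophage and NF-kB genes stood higher, and genes of replication, mitosis, ribosomes, ribosome assembly, cholesterol synthesis and the MYB and MYC leukaemia list stood lower, with members that did not pass in each. With a correlation of 0.3 between genes, 3 of the 14 list calls of day 4 held, those of the interferon, ribosomal protein and G1/S lists (adjusted p = 0.0333 each), and the highest adjusted p among the others was 0.657. Most steps were small: the median log2 fold change was 0.47 among the genes that rose and -0.39 among those that fell, and 219 reached a size of 1 (164 higher, 55 lower). The steepest rises with a mean of at least 100 in the authors' deposited table were those of MIR30A (5.22), LOX (4.31), SIGLEC1, a sialic acid receptor of macrophages (2.85), ANTXR1 (2.45), MX1 (2.15) and FOSB, an AP-1 transcription factor (1.98). After RUVBL2, the steepest falls in the authors' deposited table were VIT (-1.59), CAV1, the coat protein of caveolae (-1.50), WNT7B (-1.42), FADS2, a fatty acid desaturase (-1.32), and MS4A3 (-1.32).

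Of 31 interferon response genes 20 rose at day 4, none fell and all had a positive fold change (23 rose adjusted over the list alone; median 0.82, cameraPR adjusted p = 4.35e-18). IFI44L (2.70, adjusted p = 2.02e-08), IFIT1 (2.26, 0.00274), MX1 and IFI44 (2.03, 4.57e-05) led in the authors' deposited table. Of 37 lysosome and autophagy genes 20 rose and none fell, also adjusted over the list alone (median 0.28, adjusted p = 6.22e-12), among them GABARAPL1 (1.03), CTSK (0.87), CTSB (0.75) and CTSD (0.75) in the authors' deposited table. The monocyte and macrophage list had 18 members higher, 5 lower and 17 not passed of 40 (19 and 6 adjusted over the list alone; median 0.22, cameraPR adjusted p = 3.85e-06). ITGAM (1.46, adjusted p = 1.78e-46), GPNMB (1.37, 5.27e-31) and ITGAX (1.10, 2.17e-32) are examples of those that rose in the authors' deposited table. CSF1R, the macrophage colony stimulating factor receptor, rose by 0.60 in the authors' deposited table, while CD14 stood at 0.12 (adjusted p = 0.758). Of 21 NF-kB genes 5 rose and none fell, also adjusted over the list alone (median 0.49, adjusted p = 0.00135), with CD40 (1.14), TNFAIP3 (0.70), ICAM1 (0.69) and TNFAIP2 (0.62) rising most in the authors' deposited table. Fisher's exact test of called members did not pass for this list (adjusted p = 0.207).

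The p53 target list passed at day 4 (cameraPR adjusted p = 1.15e-04) with members moving both ways: 8 rose, 2 fell and 18 of 28 did not pass, also adjusted over the list alone, and its median was 0.05. A rank-based form of the test gave adjusted p = 0.428. The members that rose include ZMAT3 (1.43), SESN1 (1.38), CD82 (1.37) and BTG2 (1.33) in the authors' deposited table, and CDKN1A rose by 1.10 (adjusted p = 6.78e-29). BBC3, a pro-apoptotic gene of the same list, fell by 0.83 in the authors' deposited table (adjusted p = 0.0221).

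Of 53 G1/S and DNA replication genes 39 fell at day 4, none rose and all were negative (42 adjusted over the list alone; median -0.36, cameraPR adjusted p = 3.64e-21). RRM2 (-0.96, adjusted p = 2.28e-32), MCM7 (-0.74, 6.24e-27), UHRF1 (-0.72, 2.3e-11) and CDC45 (-0.57, 7.24e-07) fell furthest in the authors' deposited table. Of 59 G2/M and mitosis genes 43 fell and none rose (48 adjusted over the list alone; median -0.33, adjusted p = 2.94e-18), with AURKB (-0.75), KIF15 (-0.70), CCNB1, cyclin B1 (-0.69), and FOXM1 (-0.64) leading in the authors' deposited table. Cytosolic ribosomal protein genes fell by small and similar amounts: 62 of 75 passed, 70 adjusted over the list alone, and none was positive (median -0.24, adjusted p = 2.93e-24). RPL21 (-0.44), RPL12 (-0.38) and RPLP0 (-0.37) are examples from the authors' deposited table. Ribosomal protein genes have many near-identical pseudogene copies, between which the counting could split reads.

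Ribosome biogenesis factors fell in 19 of 37 cases at day 4, 21 adjusted over the list alone, and none rose (median -0.26, cameraPR adjusted p = 1.98e-07). NOP2 (-0.51), NOP16 (-0.42), EBNA1BP2 (-0.38) and BOP1 (-0.37) stood lowest of those in the authors' deposited table, all nucleolar assembly factors. Of 12 snoRNP proteins 4 fell, also adjusted over the list alone, namely FBL, the box C/D methyltransferase (-0.55), NOP56 (-0.47), GAR1 (-0.40) and DKC1 (-0.31) in the authors' deposited table. That list passed with adjusted p = 0.0191 (median -0.15), and had adjusted p = 0.0561 with the correlation set to 0.05. Cholesterol synthesis and uptake genes fell in 15 of 24 cases, 17 adjusted over the list alone, and all were negative (median -0.42, adjusted p = 9.39e-09). DHCR7 (-0.93), MVK (-0.74), MSMO1 (-0.67) and CYP51A1 (-0.61), all enzymes of the pathway, fell furthest in the authors' deposited table. Of 27 heat shock and chaperonin genes 12 fell and none rose (14 adjusted over the list alone; median -0.15, adjusted p = 8.58e-05), FKBP4, a co-chaperone of HSP90, furthest at -0.83 in the authors' deposited table; with the fold change as the statistic this list did not pass (adjusted p = 0.08).

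In the MYB and MYC leukaemia list 13 genes fell, 2 rose and 14 of 29 did not pass at day 4, also adjusted over the list alone (median -0.25, cameraPR adjusted p = 9.9e-07). Its members CCNB1 and BIRC5 are also in the G2/M list and CCNE1 in the G1/S list, so these list calls are not independent. MYC fell by 1.07 (adjusted p = 5.58e-29), and KIT (-0.98), FLT3 (-0.97) and MPO (-0.92) fell with it in the authors' deposited table. BCL2 fell by 0.31 (adjusted p = 1.84e-04), while MYB stood at -0.24 (adjusted p = 0.392) and HOXA9 at -0.08 (0.814) in the authors' deposited table. The integrated stress response list, high at day 2, had 3 members higher and 10 lower of 39 (3 and 13 adjusted over the list alone; median -0.18, adjusted p = 0.0191, and 0.139 with the correlation set to 0.05). In the authors' deposited table ATF3 (1.64) and NUPR1 (0.82) rose, and PYCR1, a proline synthesis enzyme (-0.75), and GPT2 (-0.64) fell.

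The other lists did not pass at day 4, although single members did. In the R2TP and TTT list (adjusted p = 0.355) ECD rose by 0.56 and RUVBL1, URI1 (-0.36) and PIH1D1 (-0.32) fell in the authors' deposited table, with 13 of 17 not passed. Of the PIKK kinases (0.178) SMG1 (0.36) and TRRAP (0.27) rose in the authors' deposited table. Among the INO80, SRCAP and TIP60 subunits (0.108) 6 fell and 1 rose of 34, YEATS4 furthest at -0.59 in the authors' deposited table. The HOXA and MEIS1 programme (0.427) had 4 higher and 5 lower of 25, with BCL11A at -0.95 in the authors' deposited table, and the apoptosis list (0.653) 5 higher and 3 lower of 34. Endoplasmic reticulum chaperones (0.653) had 4 higher and 5 lower of 25, and glycolysis and hypoxia genes (0.77) 5 higher and 5 lower of 31. Oxidative phosphorylation subunits (0.534) had 1 higher and 4 lower of 61, and granulocyte genes (0.784) 1 higher, CTSG, and 1 lower, MPO, of 11. No blood lineage marker of 8 passed (0.999), and 1 histone gene of 5 did, HIST2H2BE (0.992), at 0.83 in the authors' deposited table. Adjusted over the list alone, the counts differed for endoplasmic reticulum chaperones (7 fell), glycolysis (6 fell), oxidative phosphorylation (0 rose, 1 fell) and the remodelling subunits (5 fell). Median, mean and test differed in sign for granulocyte genes (-0.06, -0.03, up), other lineages (0.11, -0.04, up), histones (-0.32, -0.07, up), endoplasmic reticulum chaperones (0.01, -0.01, down) and glycolysis (-0.02, 0.03, down). All list calls of either day not named with a correlation of 0.05 held at that value.

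**Figure D2:**
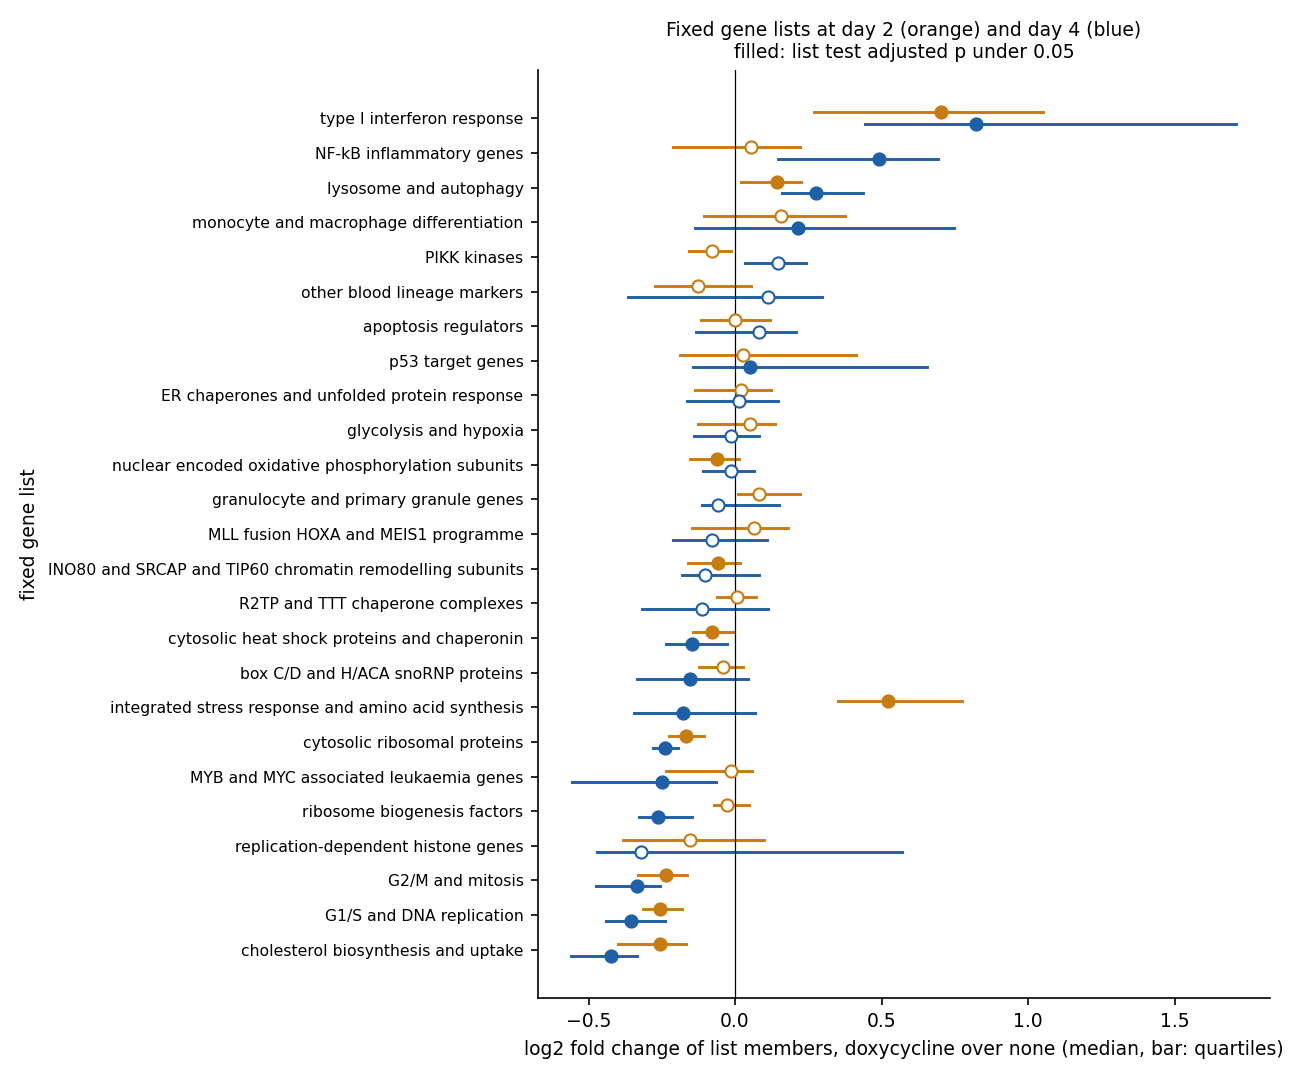
Median (points) and quartiles (bars) of the log2 fold change of each fixed gene list, doxycycline over medium alone, at day 2 (orange) and day 4 (blue), with filled points where the list test gave an adjusted p under 0.05. The interferon list lies highest on both days at 0.70 and 0.82, cholesterol synthesis lies lowest at day 4 at -0.42, and the integrated stress response list moves from 0.52 to -0.18.

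**Figure D3:**
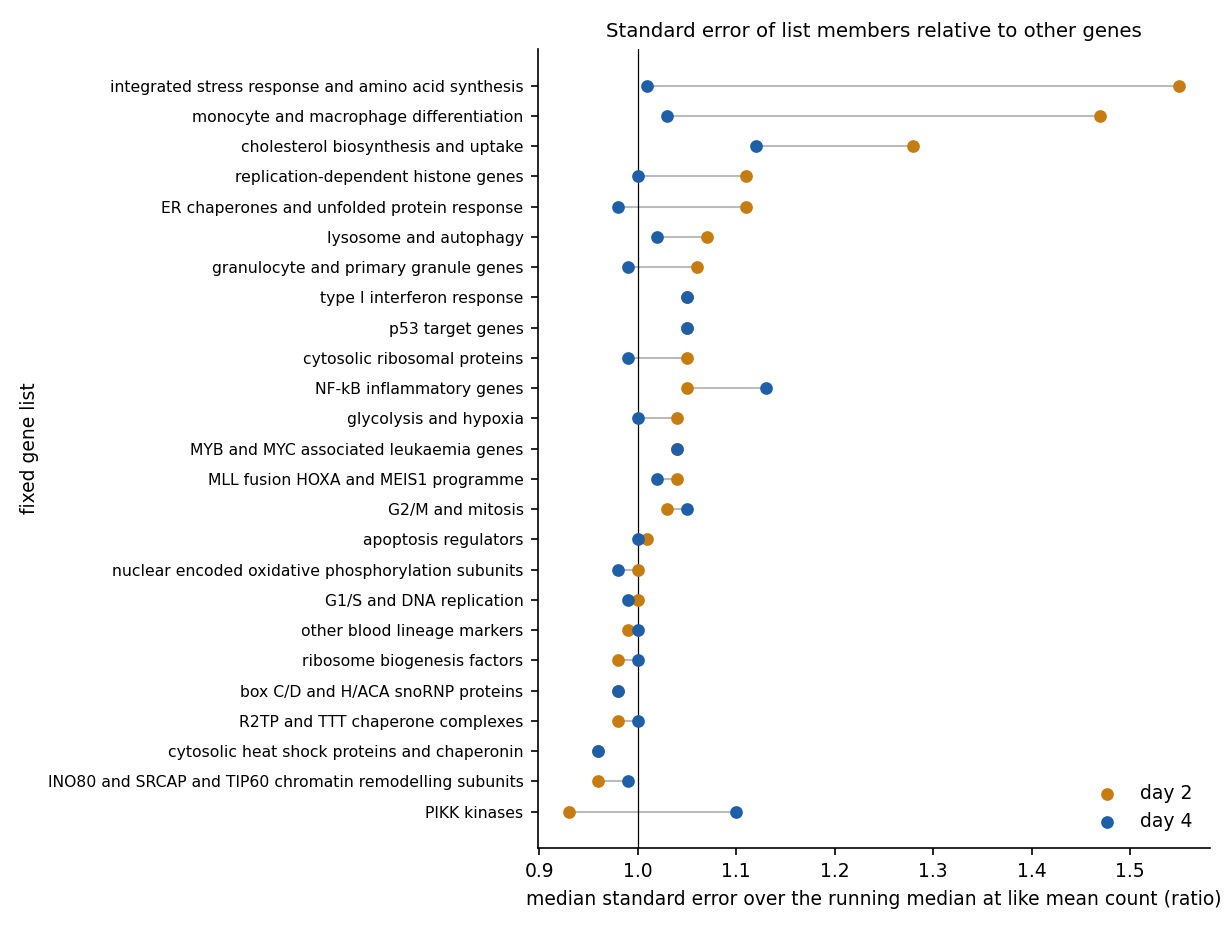
Median over list members of the standard error recovered from the authors' deposited tables, divided by the running median of genes of like mean count, at day 2 (orange) and day 4 (blue). The integrated stress response and monocyte lists stand at 1.55 and 1.47 at day 2 and at 1.01 and 1.03 at day 4.

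The 2 days were compared directly over the 12088 genes with an adjusted p in both of the authors' deposited tables, which share no library. Most of what was called at day 2 was called again at day 4: 117 of 137 genes higher at day 2 were also higher at day 4, where independent lists would share 16.4 (Fisher's exact test, two-sided p = 9.02e-88). Of 52 genes lower at day 2, 46 were lower at day 4 against 6.0 (p = 3.33e-37, Fisher's exact test). No gene was called in opposite directions, and 26 of the 189 genes called at day 2 were not called at day 4. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.575 and a Spearman rho of 0.512.

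A test of the difference between the days' log2 fold changes found 36 genes past an adjusted p of 0.05, 21 with a higher value at day 4 and 15 with a lower one. RUVBL2 was one of them: its fold change was 0.95 ± 0.19 (SE) less negative at day 4 (adjusted p = 0.00268). Among those of the 36 with a mean of at least 100 on both days, the largest downward differences were in MYC (-1.15), EIF4EBP1, a brake on translation (-0.86), MTHFD2, a mitochondrial folate enzyme (-0.78), B4GALT2 (-0.75) and ATF4 (-0.75). The largest upward ones among them, besides that of RUVBL2, were in DUSP27 (1.11), ATP8B1 (1.09), CLK1, a kinase of splicing factors (1.00), and BTG2, an antiproliferative gene (0.94). SESN1 (0.92) and RRM2 (-0.59) also passed. For ITGAM, CSF1R and CDKN1A the difference did not pass (adjusted p = 0.965, 0.937 and 0.196). The make-up of the libraries also differed between the days: cytosolic ribosomal protein genes held 10.6% of the summed mean normalised counts at day 2 and 3.49% at day 4, in tables that were normalised separately.

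**Figure D4:**
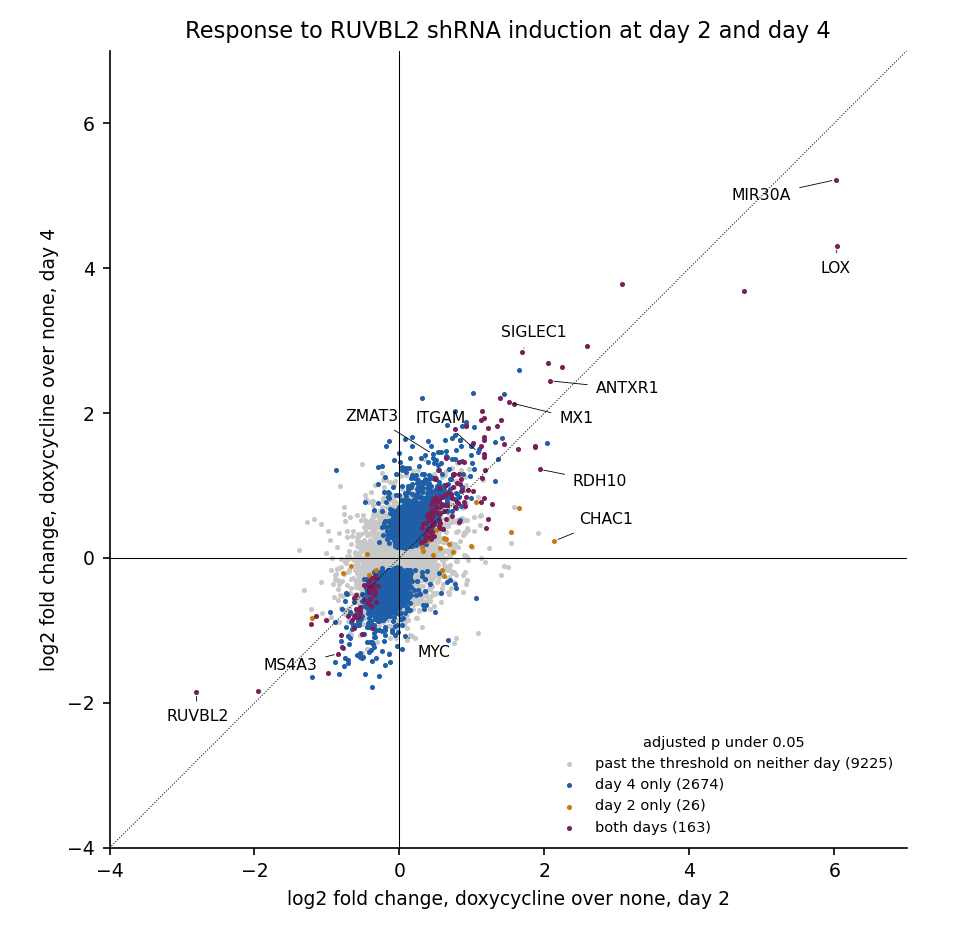
Log2 fold change at day 2 (x axis) against day 4 (y axis), doxycycline over medium alone, for the 12088 genes with an adjusted p in both of the authors' deposited tables, coloured by the days on which the authors' adjusted p was under 0.05; the dotted line marks equal values. The 163 genes called on both days lie at the upper right and lower left.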

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

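The list test of the difference between days, the comparison of summed counts as a test of depth, and all tests on chromosome 5 were chosen after the results were seen; the other tests in this part were not.

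The response to doxycycline differed between day 2 and day 4 for 36 genes, by the test of the difference itself. Among the named genes the differences (day 4 minus day 2, log2) were 0.95 for RUVBL2, -1.15 for MYC, -0.59 for RRM2, 0.92 for SESN1, 0.94 for BTG2, -0.86 for EIF4EBP1, -0.78 for MTHFD2, -0.75 for B4GALT2, -0.75 for ATF4, 1.11 for DUSP27, 1.09 for ATP8B1 and 1.00 for CLK1. Of the 36, 4 differ by 1 or more. CLK1 is not among these 4, since its difference reaches 1.00 only by rounding. A gene called on 1 day and not on the other is not shown to differ unless it is among these 36.

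As lists, 15 of the gene groups differed between the days. The integrated stress response list differed most, with a median difference of -0.66 (cameraPR adjusted p = 2.08e-22, and 8.86e-11 with the correlation set to 0.05): it was high at day 2 and not at day 4. The interferon list had a median difference of 0.41, NF-kB genes 0.33, PIKK kinases 0.30, monocyte and macrophage genes 0.22, lysosome genes 0.15 and p53 targets 0.07. Downward differences were found for ribosome biogenesis factors (-0.21), the MYB and MYC leukaemia list (-0.20), cholesterol synthesis (-0.18), snoRNP proteins (-0.12), G2/M (-0.12), G1/S (-0.11), heat shock proteins (-0.08) and cytosolic ribosomal proteins (-0.06). With the correlation set to 0.05 the difference no longer passed for cytosolic ribosomal proteins (adjusted p = 0.0926), snoRNP proteins (0.0759), the monocyte list (0.137), p53 targets (0.103) and heat shock proteins (0.162). With the fold change difference itself as the statistic it did not pass for PIKK kinases (adjusted p = 0.155), snoRNP proteins (0.323), cytosolic ribosomal proteins (0.193), G1/S (0.0584), G2/M (0.084), p53 targets (0.118) and heat shock proteins (0.361).

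The number of genes called at day 4 was 2878 against 194 at day 2. Wider errors at day 2 do not account for it alone: with noise added until each day 4 error matched that of day 2, between 1788 and 1912 genes were still called in 20 draws, against 192 at day 2 over the same 12088 genes. The 192 is the count made within this comparison, and by the authors' adjusted p 189 of these genes were called. Lower depth at day 2 is argued against by summed mean normalised counts 1.48 times those of day 4, although normalised sums only approximate depth. Larger changes at day 4 remain as a candidate explanation: with the noise taken out, the SD of the log2 fold changes was 0.276 at day 4 and 0.141 at day 2, a ratio of 1.96 (95% interval 1.62 to 2.35, 200 resamples of genes). The genes share the same libraries and are not independent, so that interval leaves out the spread between libraries. Whether more time, the return of RUVBL2 from 14.3% to 27.7%, or the handling of separate library sets underlies these larger changes was not tested.

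MIR30A rose by 6.03 and 5.22 in the authors' deposited tables. Transcription of its own locus is argued against: its host gene LINC00472 had mean normalised counts of 1.46 and 2.22, near the floor, and lay at least 3.7 standard errors of the difference below MIR30A on both days. Reads from the hairpin backbone of the vector are a candidate source, since TRIPZ carries that backbone, and this stays open. The count of other miR-30 family members that rose on both days was 0, but none of them has an adjusted p (means of at most 1.47), so that count decides nothing.

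The steepest rises gathered on chromosome 5, which was noticed by eye in a plot of the fold changes: of 8 genes that rose by at least 2 on the log2 scale on both days, PRR16, LOC102467226, LOX and ZNF608 lie within 4.28 Mb. A permutation test with a window of 5 Mb gave p = 3e-05 (2 of 100000 draws), but its size and window were set on these same genes, so it does not exclude chance. Over 24 combinations of size and window the permutation p ran from 0.0001, the smallest that 10000 draws can give, to 0.99, and was 0.05 or more in 10; at a size of 2 it was 0.0426 for 1 Mb, and at 1.5 it was 0.13 for 1 Mb. A uniform rise of the whole interval is argued against, since the 6 other genes tested there had a median of 0.13 at day 4, although PPIC among them rose on both days (0.48 and 0.68 in the authors' deposited tables), so that 5 of the 10 genes rose. Doxycycline-driven transcription from a vector copy inserted nearby may contribute to the 4 steep rises, but is not separated from chance or from an effect of RUVBL2 loss, because every sample carries the same vector.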

How the results depend on the processing

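The list tests with a correlation of 0.3 and with the length and GC trends removed were added after the data were seen, 0.3 being the 1 added correlation tried. No paired analysis was possible because the deposited tables hold no column per library; for that reason size factors, filters, other tools, pseudocounts, the replicate block, leaving out a replicate and other splits of the samples were not run. At an adjusted p under 0.01 the counts of genes were 107 (day 2), 1909 (day 4) and 9 (difference between days). With a size of at least 1 they were 52, 219 and 4. These follow from the stricter thresholds. All other gene counts stayed within 1.5 times those reported; with a mean of at least 100 the day 2 calls were 122 higher and 60 lower, against 142 and 52. Recentring on the median changed no call of a named gene, and adjustment over every gene with a p-value ended 9 such calls: FLT3 (adjusted p = 0.0561), ITGAX (0.0623), MCM4 (0.0534), ASPM (0.0511) and FDPS (0.0666) at day 2, and RUNX2 (0.0506), CASP9 (0.0708), COX7C (0.0609) and HIST2H2BE (0.0533) at day 4. The 10 lists at day 2 became 6 with the fold change as the statistic, 6 with Fisher's exact test and 4 with a correlation of 0.3; the 14 at day 4 became 3 with a correlation of 0.3. At that correlation the G1/S, G2/M, integrated stress response and interferon lists passed at day 2, and the ribosomal protein, G1/S and interferon lists at day 4. With the fold change the lists lost were, at day 2, the remodelling subunits (adjusted p = 0.297), heat shock (0.201), oxidative phosphorylation (0.199) and lysosome (0.0907), and at day 4 snoRNP (0.189), integrated stress response (0.163) and heat shock (0.08). Fisher's exact test lost ribosomal proteins (0.229), oxidative phosphorylation (0.901) and lysosome (1.00) at day 2, where the remodelling and heat shock lists had no called member to test, and snoRNP (0.0994) and NF-kB (0.207) at day 4; it gained p53 targets at day 2 (0.0337). Ranks lost snoRNP (0.06) and p53 targets (0.428) at day 4. A mean of at least 100 lost the remodelling subunits (0.0551) and gained the monocyte list (0.0258) at day 2. All 10 and all 14 kept their call after removal of the length or GC trend. Direction turned only in lists that did not pass, and none passed after turning. At day 2 these were the HOXA programme (adjusted p = 0.967 by ranks, 0.991 without the GC trend), glycolysis (0.991 without the GC trend) and NF-kB (0.92 by ranks, 0.504 with a mean of at least 100, 0.983 without the length trend). At day 4 they were granulocyte genes (0.732 with the fold change), other blood lineages (0.732 with the fold change, 0.963 without the GC trend), glycolysis (0.925 with the fold change) and histones (0.967 by ranks, 0.732 with the fold change). The cause was not tested. Depth per library is unknown, and genes with a p but no adjusted p had means of at most 5.27 (day 2) or 11.99 (day 4).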

Other observations

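The groups and measures in this part were all chosen after the fold changes were seen, as was the comparison of standard errors with random lists. Counts were looked at for 31 gene families before any was tested, so all 31 were then tested with Fisher's exact test and adjusted together over 124 tests (both directions, both days), and 9 families passed, all at day 4. The adjustment covers the 124 tests but not the choice of the families, which was made on these same fold changes. The adjusted p-values therefore describe these families and do not exclude that choice as the reason for passing. The families were taken by the start of the gene symbol, so some hold antisense or pseudogene symbols. Enzymes of purine and pyrimidine synthesis fell in 13 of 17 cases (median -0.34, adjusted p = 8.49e-08), host genes of small nucleolar RNAs in 11 of 19 (median -0.40, 3.52e-05) and chaperonin subunits in 5 of 10 (0.0411). Cathepsins rose in 8 of 13 cases (median 0.27, adjusted p = 6.56e-04), immediate-early genes such as the AP-1 factors in 8 of 16 (0.56, 0.00338), vacuolar ATPase subunits in 7 of 18 (0.0411) and Siglec receptors, which bind sialic acid on immune cells, in 5 of 10 (0.73, 0.0416). Symbols starting with ZNF held fewer calls than other genes, 16 of 435 downward (7.17e-07) and 18 upward (1.33e-06), a count that does not separate less change from wider errors. Of 77 symbols of mitochondrial ribosomal proteins, 1 of them a pseudogene, 0 were called upward (0.00235) and 15 downward, which did not pass (0.212). Cathepsins, chaperonin subunits and vacuolar ATPase subunits overlap the fixed lists. ATP6V1A and ATP6V1H, among the vacuolar ATPase subunits that rose, are also in the fixed lysosome list. The difference between days was not tested for these families.

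The spread between the day 2 libraries was uneven across genes. With a mean of at least 100, the genes whose recovered standard error most exceeded that of genes of like mean at day 2 were S100A9 and S100A8 (10.9 times or more), VCAN (7.5), IFI30 (7.3), LYZ (6.5), LSP1 (6.4), CYBB (6.1), CD14 (6.1), PSAT1 (6.0) and NPTX1 (5.7). S100A8, S100A9, VCAN, LYZ and CD14 belong to the monocyte list and PSAT1, a serine synthesis enzyme, to the stress response list. At day 4 the top genes were others, HIVEP3 (6.6), RN7SL1 (6.6) and THBD (5.4), with NPTX1 (5.3) shared. A small number of called monocyte genes at day 2 therefore goes with errors that are wide for these genes.

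The mean normalised counts had a different make-up on the 2 days, in tables normalised separately. The 10 highest genes held 7.06% of the sum at day 2 and 3.00% at day 4, and the 100 highest 22.5% and 12.5%. ACTB held 1.24% and 0.433%. Across 8255 genes with a mean of at least 100 on both days, the log2 ratio of the day 4 to the day 2 mean rose with the merged exon length of the gene (Spearman rho across genes 0.45), with a median of -0.85 in the shortest 10% and 0.01 in the longest 10%. CAP1 had the highest mean normalised count on both days in the authors' deposited tables (128348 and 42241), and PPT1, which overlaps its end on chromosome 1, ranked 5 and 3.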
